A study of Homo sapiens with 2 samples.

How the data were processed

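Gene expression was measured in HaCaT keratinocytes exposed to arsenic trioxide (0.5 µg/ml) and in unexposed cells, both at passage 22. Per the labels' protocols, RNA was reverse transcribed, amplified by in vitro transcription with amino-allyl UTP and coupled to Cy5. The scanner, background correction, normalization method and software are not given in the sources used here, nor is a genome build. Per the design text, each group had 4 RNA preparations with 3 arrays each, or 12 arrays per group.

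The authors deposited a normalized intensity per probe and group on a linear scale, with an error in the same unit. Intensity medians over all probes were 19.3 in exposed and 25.9 in passage control cells, and 822 and 1165 probes lay below 0, as after background subtraction. The deposited detection p-value gives, per the file headers, whether a probe was detected in a group. The authors' deposited table also holds a log2 ratio of exposed over control for 14401 probes, limited to 6.64 in size, and a p-value of the comparison; neither the test nor what its replicates were is stated. A second deposited set of intensities was identical to within 5.00e-07. The deposited log2 ratio is not the ratio of the deposited intensities. It exceeded that ratio by a median of 0.42 over probes detected in both groups. The median of the deposited log2 ratio itself was 0.0003, so it was already centred near 0.

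The planned test, a limma fit on the means of the RNA preparations with camera for gene lists, needs values per array or preparation and was not run. As the plan foresaw, sizes are given instead. Calls rest on the authors' deposited p-values, adjusted here by the Benjamini-Hochberg method over the genes measured, with a limit of 0.05. This use of the deposited p-values was chosen after the data were examined. The size measure was the log2 ratio of deposited intensities minus its median over probes detected in both groups (-0.43, or 1.35-fold lower in exposed cells). The 9084 probes with a detection p above 0.9 and an intensity above 5 in both groups had a median log2 ratio of -0.37 before centring. The error of a log2 ratio was propagated from both deposited errors and is no SD.

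A probe counted as detected at a detection p below 0.05. A probe detected in the brighter group alone was given a bound, with the other group set to the higher of its own value and the lowest intensity among detected probes there (54.4 in exposed, 81.7 in passage control cells). No ratio was given in other cases. A bound holds for the centred ratio used here alone, and the deposited log2 ratio can be smaller in size. Saturation is not marked in the values used here, and 17 genes above 50000 in both groups may be compressed. Compression towards 0 acts before centring, so such a ratio would lie above 0 after it. Of 7691 genes measured, 7243 were detected in both groups and 448 had a bound, and 10 had no deposited p-value. The number of arrays limits the precision; the median error of the log2 ratio was 0.21.

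Each gene was represented by its probe with the highest mean intensity. Of 30968 probes 22935 named 1 symbol, 2203 several and 5830 none. Symbols were updated through gene identifiers with RefSeq's table for the assembly GRCh38.p14. Identifiers matched for 19800 probes, 3008 without a match kept the file's symbol, and so did 127 whose identifier named another gene. The table gave names and the order of genes, and no coordinates.

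Gene lists (30) and the rule for named genes were fixed before the data were examined. The rule took, among genes called with at least 2-fold change, a level in the higher group above the median of all genes and a symbol that is no placeholder, the 12 largest rises and 12 largest falls. It added up to 4 members per list with the smallest adjusted p and the reference genes. Its condition of no overlap between preparations could not be applied. HMOX1, AKR1C2, GCLM, TKT, CCL2, FOS, EGR1, ATF3 and ATF4 are named outside the rule, after their values were seen. Some genes that the rule takes are not reported here. A list's position is the percentile of its median log2 ratio among 10000 random lists matched on mean intensity in 20 bins, which describes these values and tests nothing between cultures.

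Alternatives were quantile normalization, centring on each group's own median, an offset of 32, the mean of all probes, a 1.5-fold limit and a filter on dim genes. Others were added after the data were examined. In simulated data with a shift of -0.4, the shift was recovered as -0.40. Of 200 genes changed by 1.5 on the log2 scale among 18449 genes, 195 were recovered. Recovery needed an adjusted p below 0.05 and at least 2-fold change, and no other gene met both. The simulated p-values came from the propagated errors that also set the noise. The simulation therefore says nothing about calls made from the deposited p-values. All 5 lists shifted by 0.4 and 10 of 200 unshifted lists lay outside the percentile limits. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.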

Results

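HaCaT cells, a spontaneously immortalised line of human skin keratinocytes, were cultured with arsenic trioxide at 0.5 µg/ml up to passage 22 and compared with cells carried to passage 22 without it. The comparison asks which transcripts differ after long exposure to a skin carcinogen. Total RNA was amplified, labelled with Cy5 and hybridised to 1-colour expression arrays. The design text lists 4 RNA preparations per group, called technical replicates, with 3 arrays each, or 24 arrays in all. The deposited values hold 1 combined intensity and 1 error per probe and group, so the spread between arrays could not be examined and no test was computed from the intensities here. Each group was 1 line of cells, so exposure and drift between the lines cannot be told apart. Of 30968 probes, 10340 were detected in exposed cells and 10238 in passage control cells, and 7691 genes were measured. Exposed cells had the lower intensities, with a median log2 ratio of -0.43 over the 9915 probes detected in both groups, and changes are given relative to that median.

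AKR1C3, an aldo-keto reductase of steroid and prostaglandin metabolism, had the largest rise of all measured genes, 12.9-fold, while FBN2, which encodes the matrix protein fibrillin 2, had the largest fall among called genes, 3.71-fold. Relative to the median gene, lists of amino acid stress response, inflammatory cytokine and sterol synthesis genes were higher in exposed cells (sterol synthesis genes not without centring), and lists of MHC class I, cornified envelope and interferon-stimulated genes were lower (the interferon list not clearly so without its 2 most extreme members). A gene was called when the p-value in the authors' deposited table, adjusted here by the Benjamini-Hochberg method over 7681 genes, was below 0.05. In these terms 436 genes changed, 239 of them higher and 197 lower in exposed cells. At least 2-fold changes were found for 62 of these genes, 32 higher and 30 lower. Without centring on the median, 109 called genes passed 2-fold and 10.1% of them were higher, against 51.6% with centring. How the deposited errors and p-values were made is not stated, and the p-values measure at most the spread between preparations of 1 line per group.

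The largest rise was in AKR1C3 (chromosome 10), at an intensity of 19499 with a deposited error of 2458 in exposed cells and 2042 with an error of 133 in passage control cells. A second AKR1C3 probe read 10416 and 1393. Transcripts of the AKR1C family can share probe targets, and a probe that names AKR1C1, AKR1C2, AKR1C3 and AKR1C4 had a log2 ratio of 2.56. TNFSF18, the ligand of the receptor GITR, rose 7.22-fold from 85.0 in passage control cells, near the detection floor of 81.7. IGFL1, a secreted IGF-like protein of skin, rose 5.84-fold, with a log2 ratio of 2.55 against 2.00 in the authors' deposited table. IL1R2, the decoy receptor of interleukin 1, was not detected in passage control cells and rose at least 5.25-fold against the detection floor. That is a log2 ratio of 2.39, which the 2.30 in the authors' deposited table does not reach. CALB2, which encodes the calcium-binding protein calretinin, rose 4.12-fold from 1428 to 4363. The receptor tyrosine kinase gene AXL rose 3.39-fold with a log2 ratio of 1.76 ± 0.15, where the error is propagated from the deposited errors. F3, which encodes tissue factor, rose 2.86-fold and NRG1, which encodes the ErbB ligand neuregulin 1, rose 2.74-fold. The log2 ratio in the authors' deposited table was smaller for every rise named here. It was 3.38 against 3.68 for AKR1C3, 1.22 against 1.51 for F3 and 1.25 against 1.45 for NRG1. The deposited p-values, as adjusted here, were 1.90e-37 for AKR1C3, 7.93e-30 for AXL and 0.00954 for F3.

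Among the genes that fell, FBN2 (chromosome 5) went from 730 with an error of 48.6 in passage control cells to 146 with an error of 14.5 in exposed cells. The imprinted noncoding RNA H19 fell 3.27-fold. KRT15, a keratin of basal keratinocytes, fell 3.14-fold, and OASL, an interferon-induced gene, fell 3.02-fold. DAPK1, a death-associated protein kinase, fell 3.01-fold, and TNFSF10, which encodes the death ligand TRAIL, fell 2.48-fold. The placental alkaline phosphatase genes ALPP and ALPG, near-identical neighbours on chromosome 2 whose probes may share targets, fell 2.82-fold and 2.86-fold. PROC, which encodes the anticoagulant protein C, fell 3.21-fold, PLBD1 fell 3.05-fold and SYTL2 fell 2.48-fold. TMT1A was not detected in exposed cells and fell at least 2.52-fold. Except for ALPG and TMT1A, these falls were smaller on the log2 ratio in the authors' deposited table. It was -1.34 against -1.71 for H19 and -1.39 against -1.68 for PROC. The deposited p-values, as adjusted here, were 1.29e-13 for FBN2 and 0.0261 for PROC, the highest among these falls.

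**Figure D1:**
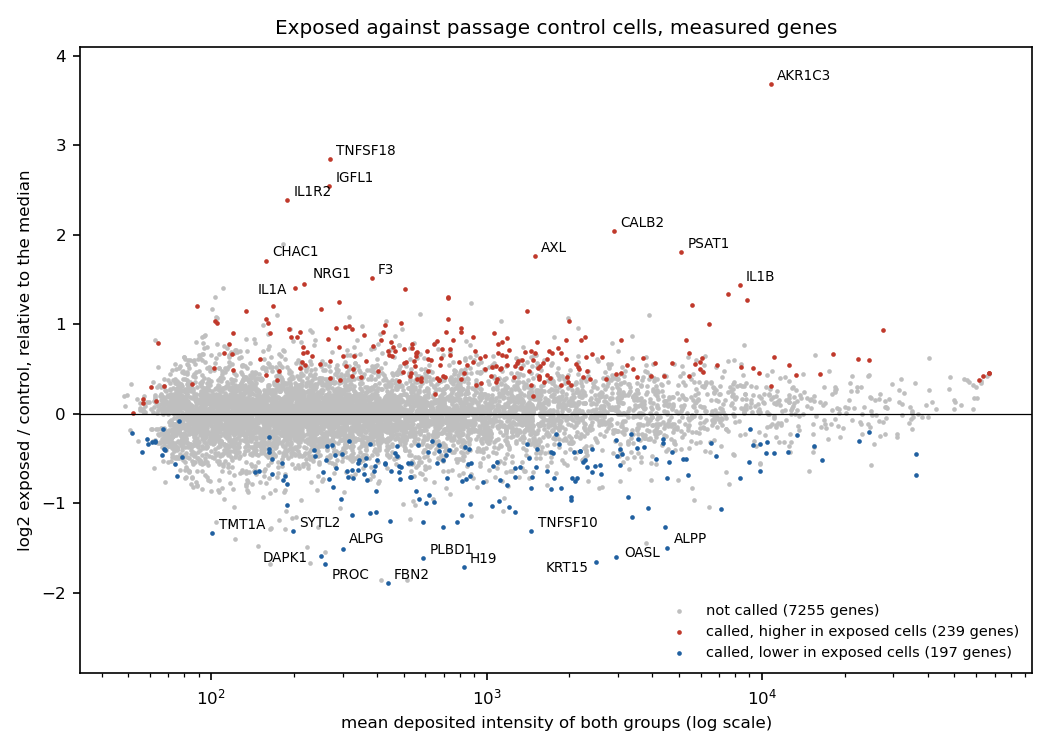
Log2 ratio of exposed over passage control cells, relative to the median, against the mean deposited intensity of both groups on a log axis, with each point 1 of 7691 measured genes and coloured points the called genes. AKR1C3 lies highest, at 3.68, and FBN2 lowest among called genes, at -1.89.

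**Figure D2:**
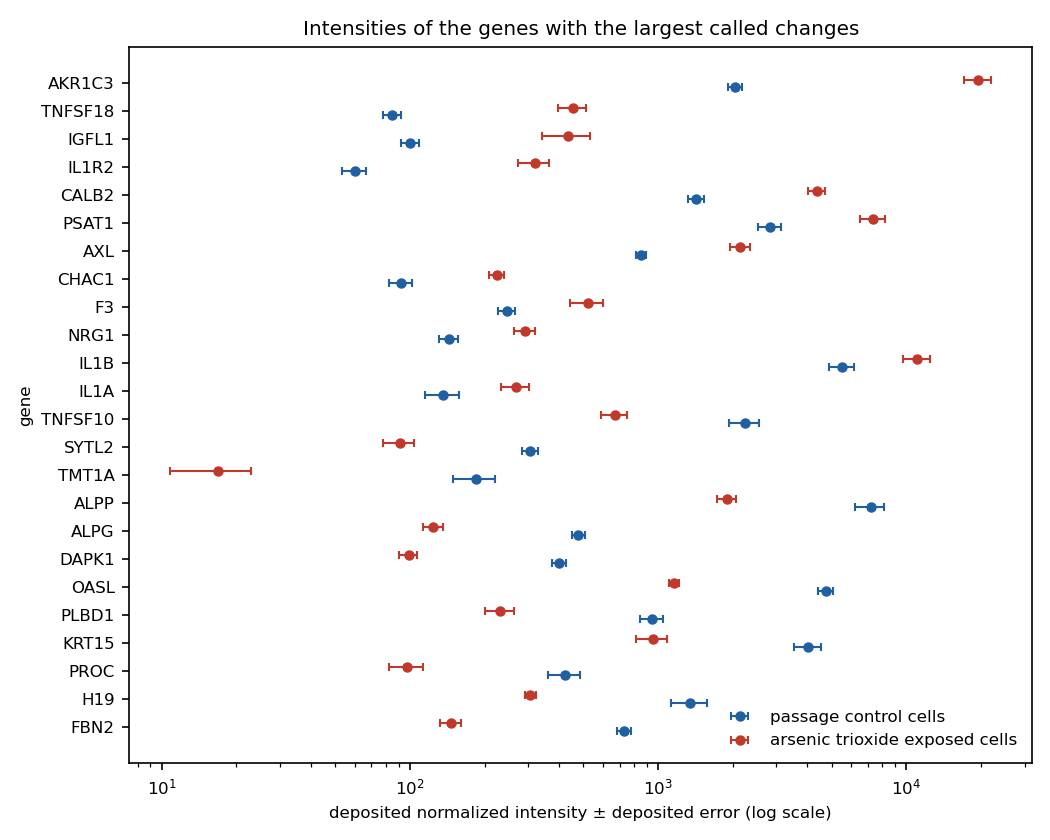
Deposited normalized intensity in exposed and passage control cells for the 12 genes with the largest called rises and the 12 with the largest called falls, on a log axis, with bars for the deposited error. The groups' error bars are apart for every gene shown, which is no separate evidence, as the genes were chosen by call and size of change. TMT1A in exposed cells and IL1R2 in passage control cells were not detected.

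NRF2 antioxidant targets, genes of glutathione, thioredoxin and pentose phosphate metabolism, lay above 0 in all 11 measured members, with a median log2 ratio of 0.61, and in 8 of 10 without centring, with a median of 0.21. AKR1C3 and PGD, a pentose phosphate enzyme gene (log2 ratio 0.58 ± 0.14), rose, none fell and 8 of the 10 with a deposited p-value did not pass. Adjusted over the list alone, 5 rose. HMOX1, which encodes heme oxygenase 1, was not detected in passage control cells, was at least 1.77-fold higher in exposed cells and had no deposited p-value. AKR1C2 and GCLM also entered the median as bounds. Genes detected in exposed cells alone could not count below 0, because they were then given no ratio. Without centring GCLM was left out for this reason. The list's median exceeded that of every one of 10000 random lists matched on intensity. TALDO1 and TKT passed adjusted over the list alone but not over all genes. Both lay near the top of the intensity range in both groups, where a compressed ratio would lie above 0 after centring. The list kept its place without TALDO1 and TKT. Metallothionein proteins bind metals and arsenic through their cysteines, and of the 2 transcripts measured MT1E had a log2 ratio of 0.27 ± 0.11 and MT2A 0.24 ± 0.19, both below 0 without centring. Neither passed over all genes, and 1 passed adjusted over the list alone. None of 6 heat shock genes passed, against 1 that fell adjusted over the list alone, and the list stood at the percentile 94.3. Among 6 measured genes of arsenic uptake, methylation and efflux, PNP, a purine nucleoside phosphorylase, rose with a log2 ratio of 0.60 ± 0.13. AQP3, an aquaglyceroporin that can carry arsenite, fell 2.13-fold (log2 ratio -1.09, or -0.94 in the authors' deposited table). Both calls were also made adjusted over the list alone. AS3MT, the arsenic methyltransferase, had a log2 ratio of -0.33 ± 0.21 and did not pass, and the list stood at the percentile 77.7.

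Integrated stress response (ATF4) targets had a median log2 ratio of 0.53, above every matched random list, or 0.10 without centring, with 9 members above 0 and 5 below. Of 14 measured members 6 rose, none fell and 8 did not pass, and adjusted over the list alone 8 rose. The serine synthesis enzyme gene PSAT1 rose 3.49-fold and CHAC1, which encodes a glutathione-degrading enzyme, rose 3.28-fold. In passage control cells CHAC1 read 91.9, near the detection floor of 81.7. The pseudokinase gene TRIB3 rose 2.52-fold and the asparagine synthetase gene ASNS rose 2.42-fold. ATF4 itself had a log2 ratio of 0.28 ± 0.49 and ATF3 of -0.82 ± 0.75, within or near their errors, and the log2 ratios in the authors' deposited table had the opposite signs, at -0.06 and 0.08. Of 9 endoplasmic reticulum chaperone and unfolded protein response genes only XBP1 rose (0.46 ± 0.11), as it did adjusted over the list alone, and that list stood at the percentile 91.7.

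Cholesterol biosynthesis genes were higher in 17 of 18 measured members, with a median of 0.33 that exceeded every matched random list, although without centring the median was -0.10 and 12 lay below 0. Of these 4 rose, among them INSIG1 (0.95 ± 0.24), SQLE (0.74 ± 0.15) and MSMO1 (0.68 ± 0.18), none fell and 14 did not pass. Adjusted over the list alone, 7 rose. Hypoxia and glycolysis genes had a median of 0.38 at the percentile 99.99, or -0.01 without centring, with 3 of 11 called as risen and 4 adjusted over the list alone. PDK1, a pyruvate dehydrogenase kinase gene, rose 2.06-fold from an intensity of 81.7 in passage control cells, which is at the detection floor. The enolase gene ENO1 had a log2 ratio of 0.38 ± 0.08, which turned to -0.046 without centring. Its intensities of 60360 and 62316 lay near the top of the range, where 17 genes above 50000 in both groups had a median log2 ratio of 0.38. Of these 4 were called higher and none lower, and compression before centring could give such values. The carbonic anhydrase gene CA9 was called from its deposited p-value, 9.60e-11 once adjusted here, and had a log2 ratio of 0.87 in the authors' deposited table. It was not detected in passage control cells, so its ratio here was a lower bound of 0.01, set by the detection floor.

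Inflammatory cytokine and NF-kB target genes had a median of 0.57, above every matched random list, or 0.14 without centring, and 6 of 14 measured members lay below 0. IL1B rose 2.71-fold, from 5510 with an error of 640 to 11094 with an error of 1379. IL1A rose 2.65-fold, the adhesion receptor gene ICAM1 rose 2.63-fold and TNF had a called log2 ratio of 0.65 ± 0.18. The other 10 did not pass, among them the chemokine gene CCL2 at -1.67 ± 0.40 (-1.14 in the authors' deposited table). Adjusted over the list alone 6 rose and 2 fell. Of 14 AP-1, immediate early and EGFR pathway genes EGFR fell (-0.32 ± 0.12), as it did adjusted over the list alone, and 13 did not pass. The list stood at the percentile 15.5. Its median error of 0.37 was larger than in every matched random list, and FOS (-0.72 ± 0.98) and EGR1 (-0.94 ± 0.76, or -0.007 in the authors' deposited table) lay within or near theirs.

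Interferon-stimulated genes had a median log2 ratio of -0.27 at the percentile 0.44. OASL, OAS1 (-0.55 ± 0.13) and IFITM1 (-0.36 ± 0.13) fell, none rose and 8 of 11 did not pass, while adjusted over the list alone 4 fell. Another 14 genes of the list with a probe were not measured. Without its 2 most extreme members the list stood at the percentile 8.45, inside the range of random lists. MHC class I antigen presentation genes were below 0 in 9 of 10 measured members, with a median of -0.23 at the percentile 0.37. HLA-B (-0.51 ± 0.18) and the immunoproteasome gene PSMB9 (-0.33 ± 0.13) fell, also adjusted over the list alone, and 8 did not pass. Probes for HLA genes can share targets.

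Epidermal differentiation and cornified envelope genes had a median of -0.23 at the percentile 1.20. The envelope genes SPRR1B (-0.99 ± 0.25) and CNFN (-0.57 ± 0.18) and the crosslinking enzyme gene TGM1 (-0.50 ± 0.13) fell. FLG, which encodes filaggrin, went the other way and rose at least 2.31-fold from a level not detected in passage control cells. That is a log2 ratio of 1.21 against the detection floor, or 1.09 in the authors' deposited table. The other 6 did not pass, and the counts adjusted over the list alone were also 3 lower and 1 higher. Among 10 basal keratinocyte genes KRT15 fell, 1 rose and 8 did not pass, with 2 higher and 2 lower adjusted over the list alone, and the list stood at the percentile 22.5. None of 9 wound keratin and alarmin genes passed under either adjustment, and that list stood at the percentile 11.1. S100A8 had a log2 ratio of -1.86 ± 0.47, or -0.97 in the authors' deposited table, without passing. None of 4 simple epithelial keratin genes passed under either adjustment, at the percentile 87.9. Of 13 epithelial junction genes the desmocollin gene DSC2 fell (-0.75 ± 0.18), also adjusted over the list alone, at the percentile 93.0. Of 8 mesenchymal genes the N-cadherin gene CDH2 rose (0.68 ± 0.19), 1 rose and 1 fell adjusted over the list alone, and the list stood at the percentile 68.1. In the matrix protease and plasminogen list the urokinase receptor gene PLAUR rose (0.92 ± 0.12) and PLAT fell (-0.97 ± 0.22), also adjusted over the list alone, at the percentile 50.6.

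No member passed under either adjustment among 17 mitosis genes (percentile 91.4), 13 DNA replication and G1/S genes (percentile 43.0), 11 p53 targets (percentile 74.9), 16 excision repair genes (percentile 94.8) or 7 DNA methylation and chromatin enzyme genes (percentile 40.1). GADD45A, a p53 target, had a log2 ratio of 1.11 ± 0.24 and did not pass. The 4 measured aryl hydrocarbon receptor targets had a median of -0.76, below every matched random list, but none passed under either adjustment. With the log2 ratio of the authors' deposited table their median was -0.37, with CYP1B1 at -1.23 and CYP1A2 at -0.10. Their median error of 0.44 stood at the percentile 99.99, and from the intensities CYP1B1 had a log2 ratio of -1.86 ± 0.43 and CYP1A2 of -0.79 ± 0.54. CYP1A2, a middle member that helps set the median, read 4556 in exposed and 10604 in passage control cells. CYP1A1 read 124 and 132. Whether the CYP1A2 probe measures that gene alone was not examined. Of 8 melanocyte, 10 fibroblast, 10 leukocyte and 6 endothelial markers, 1, 5, 4 and 1 were measured. CD14 among the leukocyte markers fell (-0.70 ± 0.18), also adjusted over the list alone, and no other marker passed. The fibroblast list stood at the percentile 23.1 and the leukocyte list at the percentile 6.53. None of 7 reference genes passed under either adjustment, with a median of -0.0003 at the percentile 43.6 and a range from -0.32 for GUSB to 0.54 for TFRC. In all, the medians of 9 of the 27 lists with 3 or more measured members lay in the lowest or highest 2.5% of matched random lists. By chance 1.35 would do so if the members of a list varied independently, which genes of 1 list need not do.

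**Figure D3:**
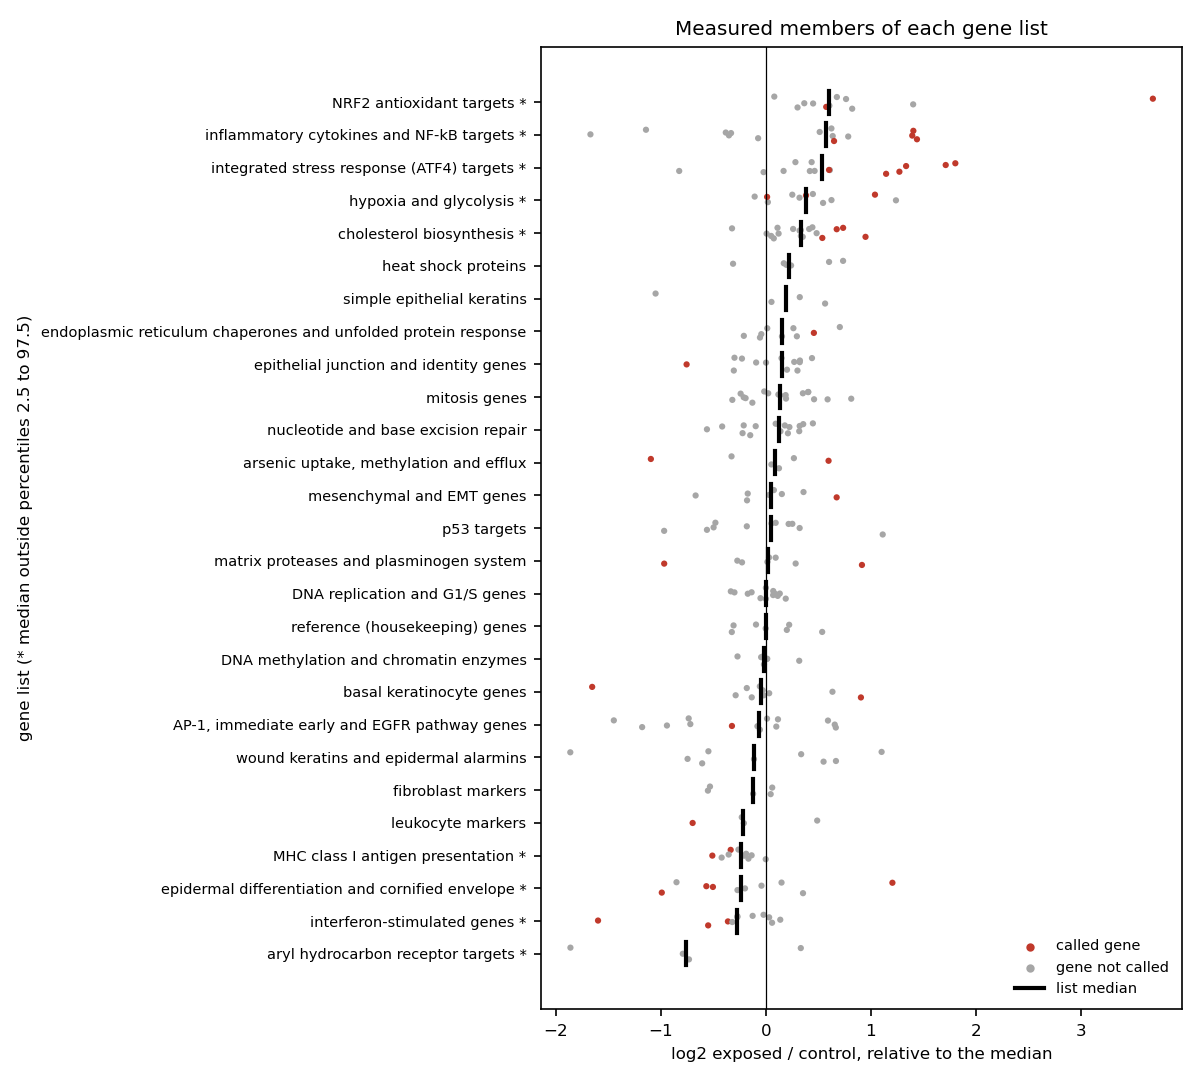
Log2 ratio of exposed over passage control cells, relative to the median, for the measured members of 27 gene lists, with red points for called genes, grey points for other genes and a black bar for each list's median. Asterisks mark the 9 lists whose median lay in the highest (5 lists) or lowest (4 lists) 2.5% of matched random lists.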

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

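Both tests of the AKR1C3 rise were chosen after its value was seen. Signal in probes outside the gene-level comparison drew attention in 3 results. Of 1155 measured probes that name no gene, 2 were called at least 2-fold higher in exposed cells and none lower. Of 964 measured probes that name several genes, 1 was called at least 2-fold higher and 1 lower. The higher of these is shared by AKR1C1, AKR1C2, AKR1C3 and AKR1C4, with a log2 ratio of 2.56 ± 0.16.

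AKR1C3 had the largest rise of all measured genes, 12.9-fold. A mean set by a few arrays is argued against, provided that the deposited error, whose basis is not stated, covers the spread between arrays as the last paragraph has it: it was at most 14.01% of the intensity over both AKR1C3 probes, where 3 of 12 arrays carrying the excess would give a standard error of at least 45.2%. Cross-hybridisation with other AKR1C genes may contribute and stays open, because no probe names AKR1C1 alone. Among detected probes of another single AKR1C gene the highest log2 ratio, for AKR1C2, was 1.40, which the limit set for this test would have counted against cross-hybridisation, but it is a lower bound from a level not detected in passage control cells; the authors' deposited table gives 0.96 for it and 0.07 for a second AKR1C2 probe, detected in neither group. The exposure itself and drift between the lines stay open as biological explanations that the design cannot separate.

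Intensities above 1000 with an error above 50% occurred in 10 probes of exposed and 6 of passage control cells, among them KLHDC8A at 1173 with an error of 1147 and AKR1C4, not detected at 5101 with an error of 4971. Of these 16 errors 14 lay between 94.2% and 107%, near the 100% of a standard error when 1 measurement carries the mean, against a median of 8.01% over all errors at such intensities.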

How the results depend on the processing

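Alternatives without centring, centring in windows of intensity, the authors' deposited log2 ratio, other p and detection limits, genes detected in both groups, brighter genes, genes below the top of the intensity range and lists without their 2 most extreme members were chosen after the data were examined. Without centring, 43.8% of called genes were higher, 109 passed 2-fold, 10.1% of those were higher, and the log2 ratio of ENO1 turned to -0.046, because the whole shift between groups then counts as change. A 1.5-fold limit gave 225 genes. An adjusted p below 0.01 gave 268 changed genes and an unadjusted p below 0.05 gave 1042, where 384 would pass by chance; both follow from the limit. Under the other alternatives, which leave the deposited p-values as they are, changed genes numbered 397 to 436. The 397 came from the filter on brighter genes, and 339 of them were among the 436. From 7 to 11 lists lay outside the percentile limits. The 7 came from leaving out the 2 most extreme members, after which the aryl hydrocarbon receptor list was too short to be placed. Of the changed genes 431 remained without genes above 50000 in both groups.

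Counting alternatives that can move the value, of 430 values of the 54 called named genes 349 moved by less than the propagated error, 80 by more and 1 reversed. Of 80 list medians 79 kept their side of the limits; the interferon list lost its place without its 2 most extreme members, at -0.14 against random lists. The planned dim filter removed no tested gene and says nothing. Not run, for want of values per array or preparation: blocked and single-array fits, other variance priors, leaving out a preparation, slide batches, camera and fry. No paired analysis was possible because each group has 1 combined column. Signal over background left 14 of 25 interferon-stimulated genes unmeasured.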

Other observations

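Of the tests below, the chance order of genes on chromosome 14, the trend with intensity and the interferon list taken alone were tested after the result was seen, and all gene groups of the next paragraph were chosen after single members had been seen, so they are no independent evidence.

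Genes of coagulation and of plasminogen activation changed in both directions. F3 (2.86-fold), the endothelial protein C receptor gene PROCR (2.33-fold), TFPI2 (2.02-fold) and PLAUR rose, while PROC and PLAT fell, with 6 of 8 measured genes called. Amino acid transporter genes lay above 0 in all 8 measured members, and in 4 without centring, and SLC1A4 (0.78 ± 0.13) and SLC3A2 (0.67 ± 0.16) rose. Their list stood at the percentile 99.89, but at 92.44 without its 2 most extreme members, inside the range of random lists. The median then fell from 0.40 to 0.19. Cytosolic aminoacyl-tRNA synthetase genes had a median log2 ratio of 0.46 over 18 genes, but 0.03 without centring with 10 above 0 and 7 below. MARS1 rose 2.01-fold, a log2 ratio of 1.01, or 0.83 in the authors' deposited table. The 11 mitochondrial synthetase genes had a median of 0.05, or -0.38 without centring with 10 below 0 and none above. As a hypothesis, cytosolic synthetases may be higher with the other ATF4 targets: their list stood at the percentile 100 and the mitochondrial list at 72.6, a contrast that could have come out otherwise. SELENOW fell 2.09-fold, but the hypothesis that selenoprotein transcripts fell as a group relative to the median gene was not borne out, since the other 14 stood at the percentile 80.5. Without centring all 14 lay below 0, with a median of -0.36, against -0.43 over all probes detected in both groups.

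Interferon-stimulated and MHC class I genes together had a median log2 ratio of -0.26 over 21 genes. As to a trend of the ratio with intensity, random lists matched on intensity had a median of 0.0245, so genes of like intensity were not lower as a set. The pooled list lay below every one of them. That place adds nothing, as each list had already lain low among such lists. The test set beforehand, centring in windows of intensity (percentile 0.01), decides nothing either, as the lists were already matched. Without OASL and OAS1 the pooled list stood at 0.09. This cannot decide whether 1 or 2 strongly changed genes set the pattern. Each list had already lain low by itself, and no MHC class I gene was removed. Taken alone without its 2 most extreme members, the MHC class I list stood at 1.62. For the interferon list alone such genes may account for its place, which moved to 8.45. EIF2AK2, an interferon-induced kinase gene outside the list named after its value was seen, rose 2.02-fold. Lower interferon signalling in exposed cells remains a hypothesis, and exposure and drift between the lines were not separated.

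A run of 30 neighbouring measured genes on chromosome 14, from LINC01588 to SNAPC1 and including HIF1A, had a median log2 ratio of 0.26 (-0.13 without centring), against 0.04 for the other 201 genes of that chromosome. Chance order is argued against, as 13 of 1000 random gene orders held a window as high anywhere (1.40% with the observed order counted), though the highest random window reached 0.31. In the other direction the lowest window, on chromosome 20 at -0.18, did not stand out, with 60.8% of orders holding one as low. Values at the detection floor are argued against as well for the run on chromosome 14. Its 24 genes detected in both groups had a median of 0.28 with the log2 ratio in the authors' deposited table. A copy number difference between the lines may account for the run and stays open: 73.3% of its genes lay above 0, short of the 75% set beforehand and above the 60% that would have argued against it. The run was picked for the highest median among 6478 windows, which by itself raises that share, so the share decides nothing. No DNA was measured.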
